A study of Mus musculus with 16 samples.

How the data were processed

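RNA sequencing was done on tumour cells enriched from mice that carried LLC1 tumours, a mouse Lewis lung carcinoma line. Mice were treated for 16 days with vehicle, TMP195, MYCi975 or both compounds, and each group holds 4 libraries, numbered 1 to 4, for 16 libraries in all. Per the labels' protocols, RNA was purified on a spin column and libraries were built with a stranded total RNA kit. The deposited table gives 24334 mouse genes as variance-stabilised values on a scale close to log2, 1 column per library. Per the submitters' processing notes, Salmon was used, without a version, and the genome build is named as hg38, although the samples and the gene identifiers are mouse. The tool behind the variance stabilisation, its settings and the mouse annotation are not given in the sources used here.

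The deposited log2 values share the same lowest value, 4.84, in every library, which is the value of a gene with no reads. A shared lowest value does not show that all effects of depth were removed. Genes at that value ranged from 1960 in Combo replicate 1 to 3130 in Vehicle replicate 4. The total count per library is unknown, and no interval or detection limit that needs a count was computed. Above the lowest value, no value occurred more than 3 times in a library. The low values thus held no steps of whole reads from which depth could be recovered. Variance stabilisation compresses differences of weakly expressed genes, so the log2 differences given here understate their fold changes. Reads shared between near-identical gene copies, such as ribosomal protein genes and their pseudogenes, or the classical and H2-Q class I genes, may have been divided between copies by the quantification, and values of single members of these families are uncertain.

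Gene symbols were taken from a table of gene names by identifier without its version, and 23150 of 24334 identifiers (95.13%) matched. Identifier versions were newer than the annotation in hand, so no coordinates are given. Gene types came from GENCODE M21, matched in the same way, and served 1 alternative and 1 test of the closing part.

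Genes were tested when their value lay at least 1 log2 unit above the lowest value in at least 4 of the 16 libraries, which left 15715 genes. A linear model with 1 mean per group was fitted to the deposited values of all 16 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. There were 6 comparisons: each treatment against vehicle, the combination against each single compound, and the interaction, which is the combination minus MYCi975 minus TMP195 plus vehicle. P-values are two-sided and were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be partly technical.

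The design, the tests, most alternatives and 52 gene lists were fixed before the data were examined. Of these lists, 36 describe pathways and 16 describe other cell types or signs of sample quality. The lists were written from general knowledge, not from these samples. Lists with at least 5 tested members were tested with camera in limma, with a preset correlation of 0.01 between genes, which covered 36 pathway lists and 9 of the others; the rest of the others had too few tested members. The pathway lists and the other lists were adjusted as separate families within each comparison. Every list was also tested with camera at an estimated correlation and with fry, which asks whether the members of a list move on balance one way and does not compare them with other genes. In addition, members were adjusted over the list alone, and an exact permutation test of the 4 against 4 list means was run, whose smallest possible p is 0.0286. The exact test was added after the data were seen.

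Genes named in the text follow a rule set beforehand. Where fewer than 5 genes were called, the 6 genes with the smallest p were taken, leaving out predicted and unnamed genes. Some genes that this rule takes are not reported here. Myc, Mycn, Mycl, Max, Hdac4, Hdac5, Hdac7, Hdac9 and Ptprc were always taken. For each called list, up to 4 members with the largest difference in the list's direction were taken, lists in order of p, to about 30 genes per comparison. Mycn is not analysed here, and Mycl was below the filter and not tested.

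The alternatives were no filter, a stricter filter (11558 genes), moderation without a trend or with robust settings, quantile normalisation, median centring, sample quality weights, replicate number as a block, the leukocyte list mean as a covariate, fitting the compared groups alone, and leaving out each library in turn. After seeing the data, 3 more were added: leaving out the 2 libraries highest in leukocyte markers, leaving out all libraries numbered 4, and using protein-coding genes alone. The test was checked on simulated values with the means and spreads of the 15715 tested genes, with 200 genes moved per draw over 5 draws. In the simulated Combo against Vehicle comparison, 21.5% of genes moved by 0.5 log2 units were recovered, 83.3% of those moved by 1 and 97.9% of those moved by 2. Over the draws, camera called lists moved by -0.2 in 6 of 10 cases and unmoved lists in 0 of 170. The simulated genes varied independently of each other. The check thus cannot show how often camera calls unmoved lists whose members vary together.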

Results

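The transcriptome of enriched LLC1 tumour cells was measured after 16 days of treatment in mice. Vehicle was DMSO, MYCi975 is a small molecule inhibitor of the transcription factor MYC, and TMP195 is an inhibitor of class IIa histone deacetylases (HDACs). Each compound was given at 50 mg/kg, and the dose of each in the combination (Combo) is not stated. There were 4 libraries in each of 4 groups. The depth per library is unknown because the values were deposited after variance stabilisation. Rank correlations between libraries ran from 0.947 to 0.969, with a median of 0.960 both within and between groups. No pair of libraries held the same values, and the smallest mean absolute difference between 2 libraries was 0.209 log2 units.

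The first principal component held 21.2% of the variance and did not separate the treatments. Replicate 4 of Vehicle, TMP195 and MYCi975 had scores of 33.2, 32.0 and 26.6, whereas Combo replicate 4 scored 5.32 and the highest of the other 12 libraries 5.90. Within every group the score rose with the replicate number. From replicate 1 to replicate 4 it ran from -13.7 to 33.2 in Vehicle and from -19.5 to 32.0 in TMP195. In MYCi975 it ran from -16.6 to 26.6, and in Combo from -18.4 to 5.32. The second component, with 14.2%, set TMP195 replicate 1 (-28.7) and MYCi975 replicate 3 (-29.1) apart from the rest.

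**Figure D1:**
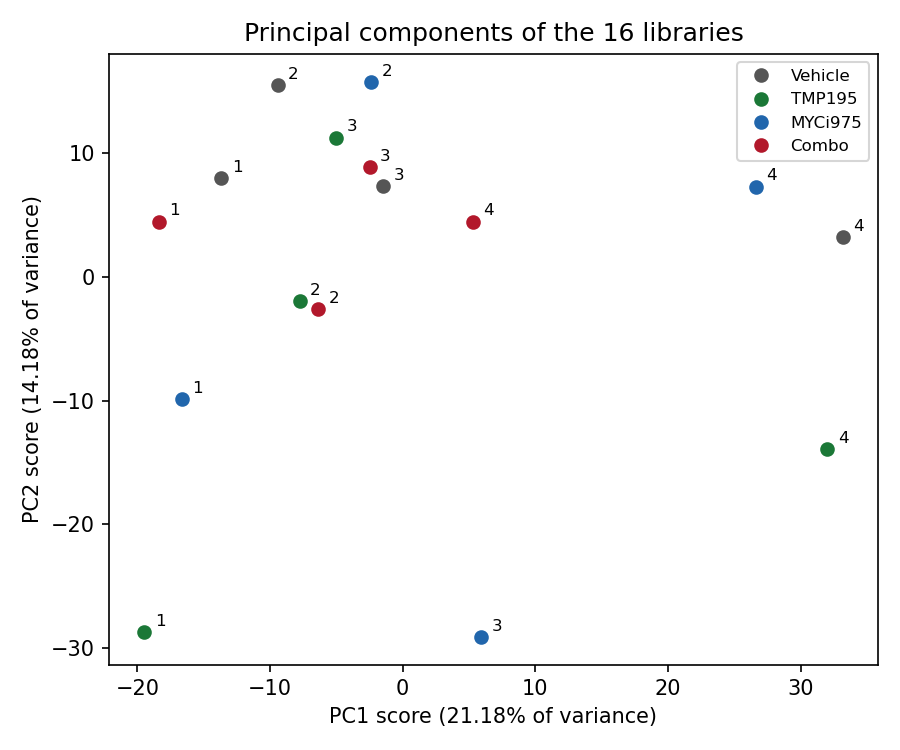
Scores of the 16 libraries on the first (x axis) and second (y axis) principal component of the 15715 tested genes, in units of the component score. Points are single libraries coloured by group and numbered by replicate, and the libraries with scores of 33.2, 32.0 and 26.6 on the first component carry number 4.

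No gene was called in any of the 6 comparisons by limma. At an unadjusted p under 0.05 there were 767 genes for TMP195 against Vehicle, 476 for MYCi975 against Vehicle, 642 for Combo against Vehicle, 365 for Combo against MYCi975, 837 for Combo against TMP195 and 471 for the interaction, between 2.32% and 5.33% of the genes tested. The median standard error of a log2 difference between groups was 0.157, with a 95% confidence interval of 0.332 on either side. The results below are therefore about gene lists, and the genes named are examples that did not pass the test alone.

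The drug targets themselves were first compared. Myc (ENSMUSG00000022346.18) differed from Vehicle by 0.08 in TMP195, -0.21 in MYCi975 and -0.24 in Combo, each with a standard error (SE) of 0.21. Its dimerisation partner Max differed by -0.04, -0.05 and -0.01 (SE 0.12). Of the class IIa HDAC genes, Hdac9 (ENSMUSG00000004698.12) was higher by 0.35 (SE 0.14, limma adjusted p = 0.945) in TMP195 in 4 of 4 libraries, and by 0.19 in Combo. Hdac4, Hdac5 and Hdac7 differed from Vehicle by between -0.14 and 0.08 in every treatment. The list of class IIa HDACs and MEF2 factors was not called against Vehicle, with medians of 0.03 in TMP195, -0.11 in MYCi975 and -0.03 in Combo.

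TMP195 was compared with Vehicle to ask what class IIa HDAC inhibition does to tumour cells in the animal. Genes of cell division were lower and genes of the hypoxia response higher in the TMP195 group, but library means overlapped for these lists. For DNA replication TMP195 replicate 3 (10.111) lay above Vehicle replicates 1 and 3 (10.054 and 10.004). For mitosis TMP195 replicates 3 and 4 (10.689 and 10.682) lay above Vehicle replicates 1 and 3 (10.656 and 10.506). Neither was among the 2 pathway lists with an exact permutation p under 0.05 in this comparison. Of 44 genes of DNA replication and entry into S phase, 43 were lower, with a median difference of -0.21 (camera adjusted p = 1.56e-10; adjusted p = 0.363 with an estimated correlation). Examples are E2f2 (-0.59, SE 0.23), Ccne1, a cyclin that starts S phase (-0.45, SE 0.14), Prim1 (-0.42, SE 0.18) and Mcm10 (-0.41, SE 0.15). Of 38 mitosis genes, 37 were lower with a median of -0.24 (adjusted p = 6.26e-09; adjusted p = 0.411 with an estimated correlation), among them Kif4 (-0.36), Nuf2 (-0.35), Anln (-0.35) and the kinase Aurkb (-0.33).

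MYC target genes were lower in TMP195, with 53 of 59 below Vehicle (median difference -0.14, camera adjusted p = 3.31e-08; adjusted p = 0.274 with an estimated correlation). The means of this list in the 4 TMP195 libraries, 10.28 ± 0.02 (SD, n = 4), all lay below those of Vehicle, 10.42 ± 0.04 (exact permutation p = 0.0286, adjusted p = 0.513 over 36 lists). Tmem97 (-0.46, SE 0.12), Rabepk (-0.36), the mitochondrial RNA helicase Supv3l1 (-0.34) and Umps of pyrimidine synthesis (-0.34) differed most. Genes of mitochondrial ribosomal proteins were lower in 72 of 78 cases (median -0.13, adjusted p = 2.63e-07; adjusted p = 0.274 with an estimated correlation), for example Mrpl57 (-0.42) and Mrpl4 (-0.39). Cholesterol synthesis was lower in 21 of 23 genes (median -0.24, adjusted p = 1.4e-06; adjusted p = 0.411 with an estimated correlation), with Cyp51 (-0.43) and Hmgcs1 (-0.36) as examples.

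Hypoxia response genes were higher in 22 of 24 cases (median 0.26, camera adjusted p = 1.69e-07; adjusted p = 0.363 with an estimated correlation). The list means of the libraries overlapped between the groups (exact permutation p = 0.2, adjusted p = 0.55). TMP195 replicates 2 and 3 had means of 11.466 and 11.377, and replicates 1 and 4 had 10.915 and 10.992. Vehicle replicates 1, 2, 3 and 4 had 11.016, 10.715, 11.203 and 10.684. Car9 (ENSMUSG00000028463.15), a carbonic anhydrase induced by low oxygen, differed by 0.92 (SE 0.20, limma adjusted p = 0.904), and it alone passed when adjusted over the list alone. The vasodilator peptide gene Adm differed by 0.69 (SE 0.26), Ndrg1 by 0.56 and Ero1l by 0.50. The other called lists were purine and pyrimidine synthesis, mitochondrial import, cytosolic ribosomal proteins, ribosome biogenesis, respiratory complex IV and the interferon response, all lower, with medians from -0.22 for the interferon response to -0.09 for ribosomal proteins. Their adjusted p with an estimated correlation ran from 0.274 to 0.686. Without all libraries numbered 4, a choice made after the data were seen, the interferon response (0.122, above 0), ribosomal proteins (-0.031), import (-0.071) and complex IV (-0.067) were not called. The mitochondrial ribosome was then called at -0.086.

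Leukocyte markers were also higher in the TMP195 group, but not library by library with the hypoxia genes. TMP195 replicate 1 had a mean of 8.084 for all leukocytes and 10.915 for hypoxia response. TMP195 replicate 3 had 6.870 and 11.377. Of 12 macrophage and monocyte markers, 11 were higher with a median of 0.50 (camera adjusted p = 2.1e-09; adjusted p = 0.0574 with an estimated correlation), and 5 passed when adjusted over the list alone. Of 9 markers of all leukocytes, 8 were higher with a median of 0.75 (adjusted p = 1.31e-06; adjusted p = 0.0936 with an estimated correlation), and 4 passed when adjusted over the list alone. Ptprc (ENSMUSG00000026395.17), which encodes the leukocyte surface protein CD45, differed by 1.13 (SE 0.43, limma adjusted p = 0.945) and was above the Vehicle mean in 4 of 4 libraries. Neutrophil markers had a median of 0.55 (adjusted p = 0.000213; adjusted p = 0.186 with an estimated correlation) and dendritic cell and MHC class II markers 0.27 (adjusted p = 0.000163; adjusted p = 0.0936 with an estimated correlation). With the leukocyte covariate, which takes out the level of these markers by construction, those of all leukocytes (0.019), dendritic cells (0.115) and neutrophils (-0.023) were not called. Macrophage markers were then called at 0.159, and mitosis and cholesterol synthesis at -0.141 each. The gene with the smallest p was Cd93 (ENSMUSG00000027435.9), a surface receptor of myeloid and endothelial cells, which differed by 1.004 (SE 0.16, limma adjusted p = 0.139). It was followed by the chemokine gene Cxcl3 (1.45, SE 0.32), Car9, Xylt1 (0.98), the neutrophil collagenase Mmp8 (0.74) and F10 (0.99), each with an adjusted p of 0.904. Replication-dependent histones were lower in 53 of 57 cases with a median of -0.36 (camera adjusted p = 1.41e-12; adjusted p = 0.144 with an estimated correlation), and early stress genes of dissociation in 16 of 19 with a median of -0.27 (adjusted p = 0.001; adjusted p = 0.295 with an estimated correlation).

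Of the 12 pathway lists called for TMP195 against Vehicle, 11 were lower and 1 higher, and none was called with an estimated correlation or by fry. Without TMP195 replicate 3, the macrophage receptor genes Csf1r (1.60, adjusted p = 0.003) and Ccr2 (1.66, adjusted p = 0.0182) were called by limma, both picked here after their values were seen. Without Vehicle replicate 4, ribosomal proteins (median -0.009), the interferon response (-0.039), mitochondrial import, complex IV and early stress genes (-0.168) were not called. DNA replication (-0.139), cholesterol synthesis (-0.143) and the mitochondrial ribosome (-0.08) were then called with smaller medians. Ribosomal proteins were also not called without TMP195 replicate 3, and the interferon response without Vehicle replicate 2 or TMP195 replicate 4. Medians moved by over 1.5 times, with the call kept, for mitosis without Vehicle replicate 2 (-0.151), hypoxia response without TMP195 replicate 2 (0.152), and all leukocytes (0.416), macrophages (0.327) and histones (-0.194) without TMP195 replicate 1. Without the 2 libraries highest in leukocyte markers, TMP195 replicate 1 and MYCi975 replicate 3, these last 3 values were the same by construction. MYCi975 replicate 3 is not in this comparison.

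**Figure D2:**
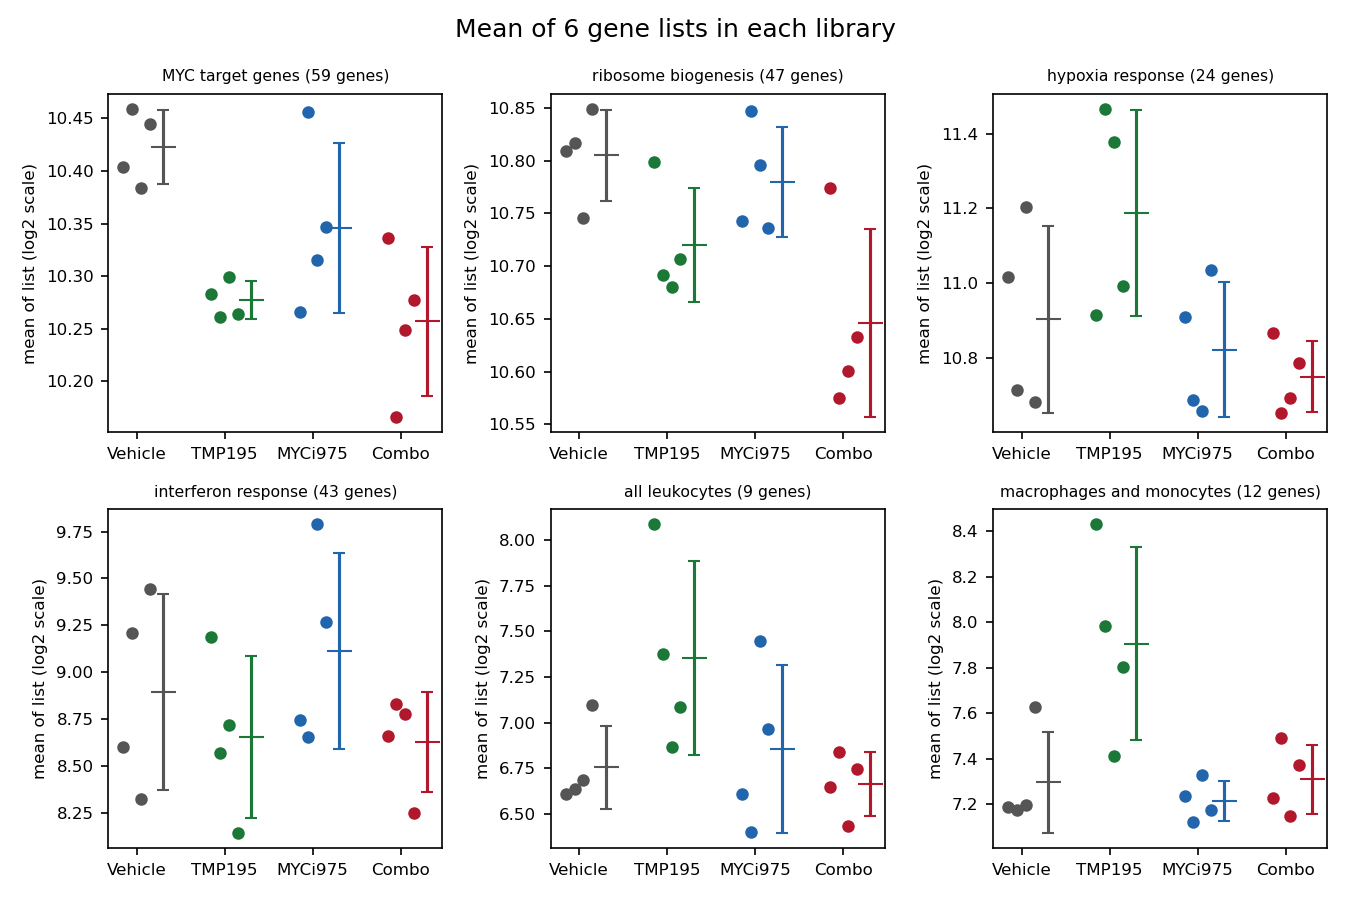
Mean of 6 gene lists (y axis, log2 scale, not starting at 0) in each library by group (x axis), with points for single libraries and a dash and bar for the group mean and SD (n = 4). MYC target genes lie at 10.42 ± 0.04 in Vehicle and 10.26 ± 0.07 in Combo, and macrophage and monocyte markers at 7.91 ± 0.42 in TMP195 and 7.31 ± 0.15 in Combo.

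MYCi975 was compared with Vehicle to ask what MYC inhibition does. Genes of antioxidant defence, sterol synthesis, glycolysis and mitosis were lower in the MYCi975 group and interferon genes higher. Of 27 NRF2 and antioxidant genes, 26 were lower with a median of -0.20 (camera adjusted p = 8.08e-08; adjusted p = 0.408 with an estimated correlation), including Gsta4 (-0.53, SE 0.27), the cystine transporter Slc7a11 (-0.52, SE 0.27), Nqo1 (-0.40) and Gclc, of glutathione synthesis (-0.36, SE 0.11). All 23 cholesterol synthesis genes were lower, with a median of -0.22 (adjusted p = 2.22e-07; adjusted p = 0.613 with an estimated correlation), for example Fdps (-0.49) and Mvk (-0.31). Glycolysis genes were lower in 20 of 23 cases, with a median of -0.23 (adjusted p = 1.12e-06; adjusted p = 0.573 with an estimated correlation), including Pdk1 (-0.51, SE 0.19), Pgam1 (-0.39, SE 0.12), Pgk1 (-0.36) and lactate dehydrogenase Ldha (-0.32).

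Mitosis genes were lower in 37 of 38 cases (median -0.15, camera adjusted p = 7.08e-06; adjusted p = 0.674 with an estimated correlation), and integrated stress response genes in 28 of 30 (median -0.14, adjusted p = 5.74e-05; adjusted p = 0.408 with an estimated correlation), with Psat1 of serine synthesis at -0.42 (SE 0.17) and Cth at -0.48. MYC target genes were lower in 46 of 59 cases with a median of -0.07 (adjusted p = 0.00459; adjusted p = 0.638 with an estimated correlation), for example Rabepk (-0.34), Plk4 (-0.28) and Mrto4 (-0.27). Ribosome biogenesis was not called (median -0.03, adjusted p = 0.541). DNA replication, proteasome, mitochondrial import and nucleotide synthesis were also called as lower, with medians from -0.14 to -0.06 and adjusted p from 0.493 to 0.674 with an estimated correlation. Interferon response genes were higher in 36 of 43 cases, with a median of 0.19 (adjusted p = 2.47e-05; adjusted p = 0.674 with an estimated correlation), including Oas2 (0.65, SE 0.33), Rsad2 (0.64, SE 0.29), Ifit1 (0.63) and Irf7 (0.56). Without MYCi975 replicate 3 the median of the interferon response was below 0, at -0.025, and the list was not called.

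Neutrophil markers were higher in 7 of 8 cases in MYCi975, with a median of 0.37 (camera adjusted p = 0.0244; adjusted p = 0.805 with an estimated correlation), and their mean was 7.91 in MYCi975 replicate 3 against 6.17 to 6.85 in the other 3. The genes with the smallest p were Ttll3 (0.65, SE 0.16), AY512931 (0.53), Olfr1156 (0.57), Ikzf2 (0.81), Hspb6 (-0.54) and Pcdhga2 (0.44), each with a limma adjusted p of 0.999. Of 11 called pathway lists, 10 were lower, and none was called with an estimated correlation or by fry. Without Vehicle replicate 4, DNA replication (median -0.032), import (-0.021), the proteasome (-0.025) and nucleotide synthesis were not called. Without MYCi975 replicate 1 the same held for DNA replication, the proteasome, nucleotide synthesis and MYC target genes. Nucleotide synthesis was also not called without Vehicle replicate 2 (-0.037) or MYCi975 replicate 3 or 4. The interferon response lost its call without Vehicle replicate 3, and neutrophil markers without MYCi975 replicate 3 (0.09) or Vehicle replicate 2 or 3. Without Vehicle replicate 2, MYC target genes (-0.041), the integrated stress response (-0.059) and mitosis (-0.092) were called with smaller medians, mitosis also without Vehicle replicate 4. With quantile normalisation MYC target genes (-0.046, adjusted p = 0.055), the proteasome (-0.07), nucleotide synthesis (-0.07) and neutrophil markers (0.34) were not called, and 8 pathway lists were. With the leukocyte covariate nucleotide synthesis (-0.086) was not called. Of the settings chosen after the data were seen, the one without the 2 libraries highest in leukocyte markers ended the calls of the interferon response (-0.025), nucleotide synthesis (-0.051) and neutrophil markers (0.09). Its medians are by construction those without MYCi975 replicate 3, since the other library is not in this comparison. The one without all libraries numbered 4 ended those of cholesterol synthesis (-0.063), DNA replication (-0.05), import (-0.045), the proteasome (-0.037) and nucleotide synthesis (-0.042), with mitosis called at -0.082. Without MYCi975 replicate 1, 7 pathway lists were called, and without MYCi975 replicate 2, 1 predicted gene, Gm15801, named here after its value was seen, was called by limma (1.77, adjusted p = 0.0431).

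Combo was compared with Vehicle to ask what inhibiting MYC and class IIa HDACs together does, a question the series ties to mitochondrial function. Lists of MYC targets, ribosome biogenesis, some mitochondrial functions and antigen presentation were among those called as lower in Combo. MYC target genes were lower in 54 of 59 cases, with a median of -0.16 (camera adjusted p = 4.66e-10; adjusted p = 0.107 with an estimated correlation; fry adjusted p = 0.0262), and the 4 Combo means, 10.26 ± 0.07 (SD, n = 4), lay below all 4 of Vehicle (exact permutation p = 0.0286, adjusted p = 0.343). Examples are Rrp9 (-0.42, SE 0.20), Nolc1 (-0.41), Supv3l1 (-0.40, SE 0.12) and Ppan (-0.38, SE 0.14), most of them in ribosome assembly. Ribosome biogenesis was lower in 43 of 47 genes with a median of -0.15 (adjusted p = 1.51e-08; adjusted p = 0.107 with an estimated correlation; fry adjusted p = 0.0333), including Dkc1 (-0.42, SE 0.16), Nop14 (-0.40, SE 0.16) and Utp4 (-0.36, SE 0.11). No member of either list passed over all genes or when adjusted over the list alone.

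Of the mitochondrial lists, 6 were called as lower in Combo. None of these was called for Combo against TMP195. Group means in Vehicle, TMP195 and Combo were 8.91, 8.78 and 8.82 for the mitochondrial ribosome. They were 9.49, 9.36 and 9.38 for import, and 9.86, 9.72 and 9.76 for complex IV. For mitochondrial DNA maintenance they were 9.282, 9.196 and 9.195. Combo lay below TMP195 for genes of the mitochondrial genome (13.03 against 13.18) and chaperones (10.86 against 10.90). Genes of mitochondrial ribosomal proteins were lower in 63 of 78 cases (median -0.10, camera adjusted p = 0.000112; adjusted p = 0.389 with an estimated correlation), for example Mrpl57 (-0.40) and Mrps18b (-0.36, SE 0.10). Import genes were lower in 22 of 28 cases (median -0.12, adjusted p = 0.00372; adjusted p = 0.322 with an estimated correlation), including Timm23 (-0.31, SE 0.12). The 13 protein genes of the mitochondrial genome had a median of -0.24, 11 of them lower (adjusted p = 0.015; adjusted p = 0.522 with an estimated correlation), with mt-Atp6 at -0.66 (SE 0.32) and mt-Nd1 at -0.41 (SE 0.20). Mitochondrial chaperones and proteases were lower in 10 of 15 cases (median -0.13, adjusted p = 0.0397; adjusted p = 0.288 with an estimated correlation; fry adjusted p = 0.0156), among them Clpp (-0.22) and Lonp1 (-0.17). Respiratory complex IV (median -0.10, adjusted p = 0.389 with an estimated correlation) and mitochondrial DNA maintenance (median -0.08, adjusted p = 0.389 with an estimated correlation) were also called. Complex I (median -0.09, camera adjusted p = 0.1), complexes II and III (-0.06, adjusted p = 0.565), ATP synthase (-0.10, adjusted p = 0.0842), the TCA cycle (-0.06, adjusted p = 0.131), biogenesis regulators (-0.04, adjusted p = 0.352), dynamics and mitophagy (-0.05, adjusted p = 0.255) and fatty acid oxidation (0.03, adjusted p = 0.362) were not.

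Immune lists were lower too. MHC class I antigen presentation was lower in 20 of 21 genes, with a median of -0.37 (camera adjusted p = 3.14e-06; adjusted p = 0.404 with an estimated correlation), including the transactivator Nlrc5 (-0.77, SE 0.36), H2-K1 (-0.55) and B2m (-0.51). Interferon response genes had a median of -0.29 (adjusted p = 0.000302; adjusted p = 0.552 with an estimated correlation), and NF-kB and inflammatory genes -0.23 (adjusted p = 0.000179; adjusted p = 0.404 with an estimated correlation). The integrated stress response was lower in 26 of 30 genes with a median of -0.21 (adjusted p = 3.8e-05; adjusted p = 0.211 with an estimated correlation), with Trib3 at -0.50 (SE 0.20). DNA replication (-0.18), mitosis (-0.16), glycolysis (-0.18), cholesterol synthesis (-0.17), hypoxia response (-0.16), NRF2 (-0.15), nucleotide synthesis (-0.14), ribosomal proteins (-0.12) and the proteasome (-0.08) completed the 21 called pathway lists, all lower, with adjusted p from 0.389 to 0.467 with an estimated correlation. With quantile normalisation 15 were called, without genes of the mitochondrial genome (-0.211, adjusted p = 0.0658), mitochondrial chaperones (-0.09), complex IV (-0.064), mitochondrial DNA maintenance (-0.049), nucleotide synthesis (-0.091) and the proteasome (-0.04). Markers of all leukocytes had a median of -0.11 and were not called (camera adjusted p = 0.639). Fibroblast markers were higher in 10 of 12 cases with a median of 0.34 (adjusted p = 0.002; adjusted p = 0.407 with an estimated correlation), and histones lower with a median of -0.24 (adjusted p = 3.14e-07; adjusted p = 0.407 with an estimated correlation). Among the genes with the smallest p were Pik3r1 (0.64, SE 0.16), the ribosome biogenesis helicase Ddx21 (-0.35, SE 0.09), Zbtb20 (0.64) and Ror1 (0.59), each with a limma adjusted p of 0.987.

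With an estimated correlation none of the 21 pathway lists was called, and fry called 3 of the 36. MYC target genes and ribosome biogenesis were called without any 1 library, with medians nearest 0 of -0.126 and -0.11, both without Combo replicate 2. Genes of the mitochondrial genome were not called without Vehicle replicate 3 (median -0.09), Vehicle replicate 1 or Combo replicate 3, and hypoxia response not without Vehicle replicate 3 (-0.067) or 1, its median also moving by over 1.5 times without Combo replicate 2. Without Vehicle replicate 4, cholesterol synthesis (-0.063), the interferon response (-0.083), chaperones (-0.075), mitochondrial DNA maintenance (-0.065), import, complex IV, the proteasome and nucleotide synthesis were not called. MHC class I (-0.153), DNA replication (-0.09), ribosomal proteins (-0.055) and histones (-0.155) were then called with smaller medians, histones also without Vehicle replicate 2. Calls were also lost for chaperones without Vehicle replicate 1 or 3 or Combo replicate 1 or 2, and for mitochondrial DNA maintenance without Vehicle replicate 1 or Combo replicate 1 or 4. So they were for complex IV without Vehicle replicate 1 or 2 (-0.072) or Combo replicate 2. The same held for the interferon response without Vehicle replicate 2 or Combo replicate 4, nucleotide synthesis without Vehicle replicate 2 (-0.096) or Combo replicate 2, and the proteasome without Combo replicate 2 (-0.021). The integrated stress response was at -0.103 without Vehicle replicate 2, and NRF2 (-0.078) and glycolysis (-0.115) without Combo replicate 2. Without Vehicle replicate 4 camera called 13 pathway lists, and without all libraries numbered 4, a choice made after the data were seen, it called 12. Not called there were the interferon response (0.02, above 0), MHC class I (-0.054), cholesterol synthesis (-0.063), import (-0.06), mitochondrial DNA maintenance (-0.095), chaperones (-0.126), complex IV (-0.086), the proteasome (-0.049) and nucleotide synthesis (-0.09). DNA replication (-0.093), ribosomal proteins (-0.075) and fibroblast markers (0.226) were called with medians nearer 0.

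**Figure D3:**
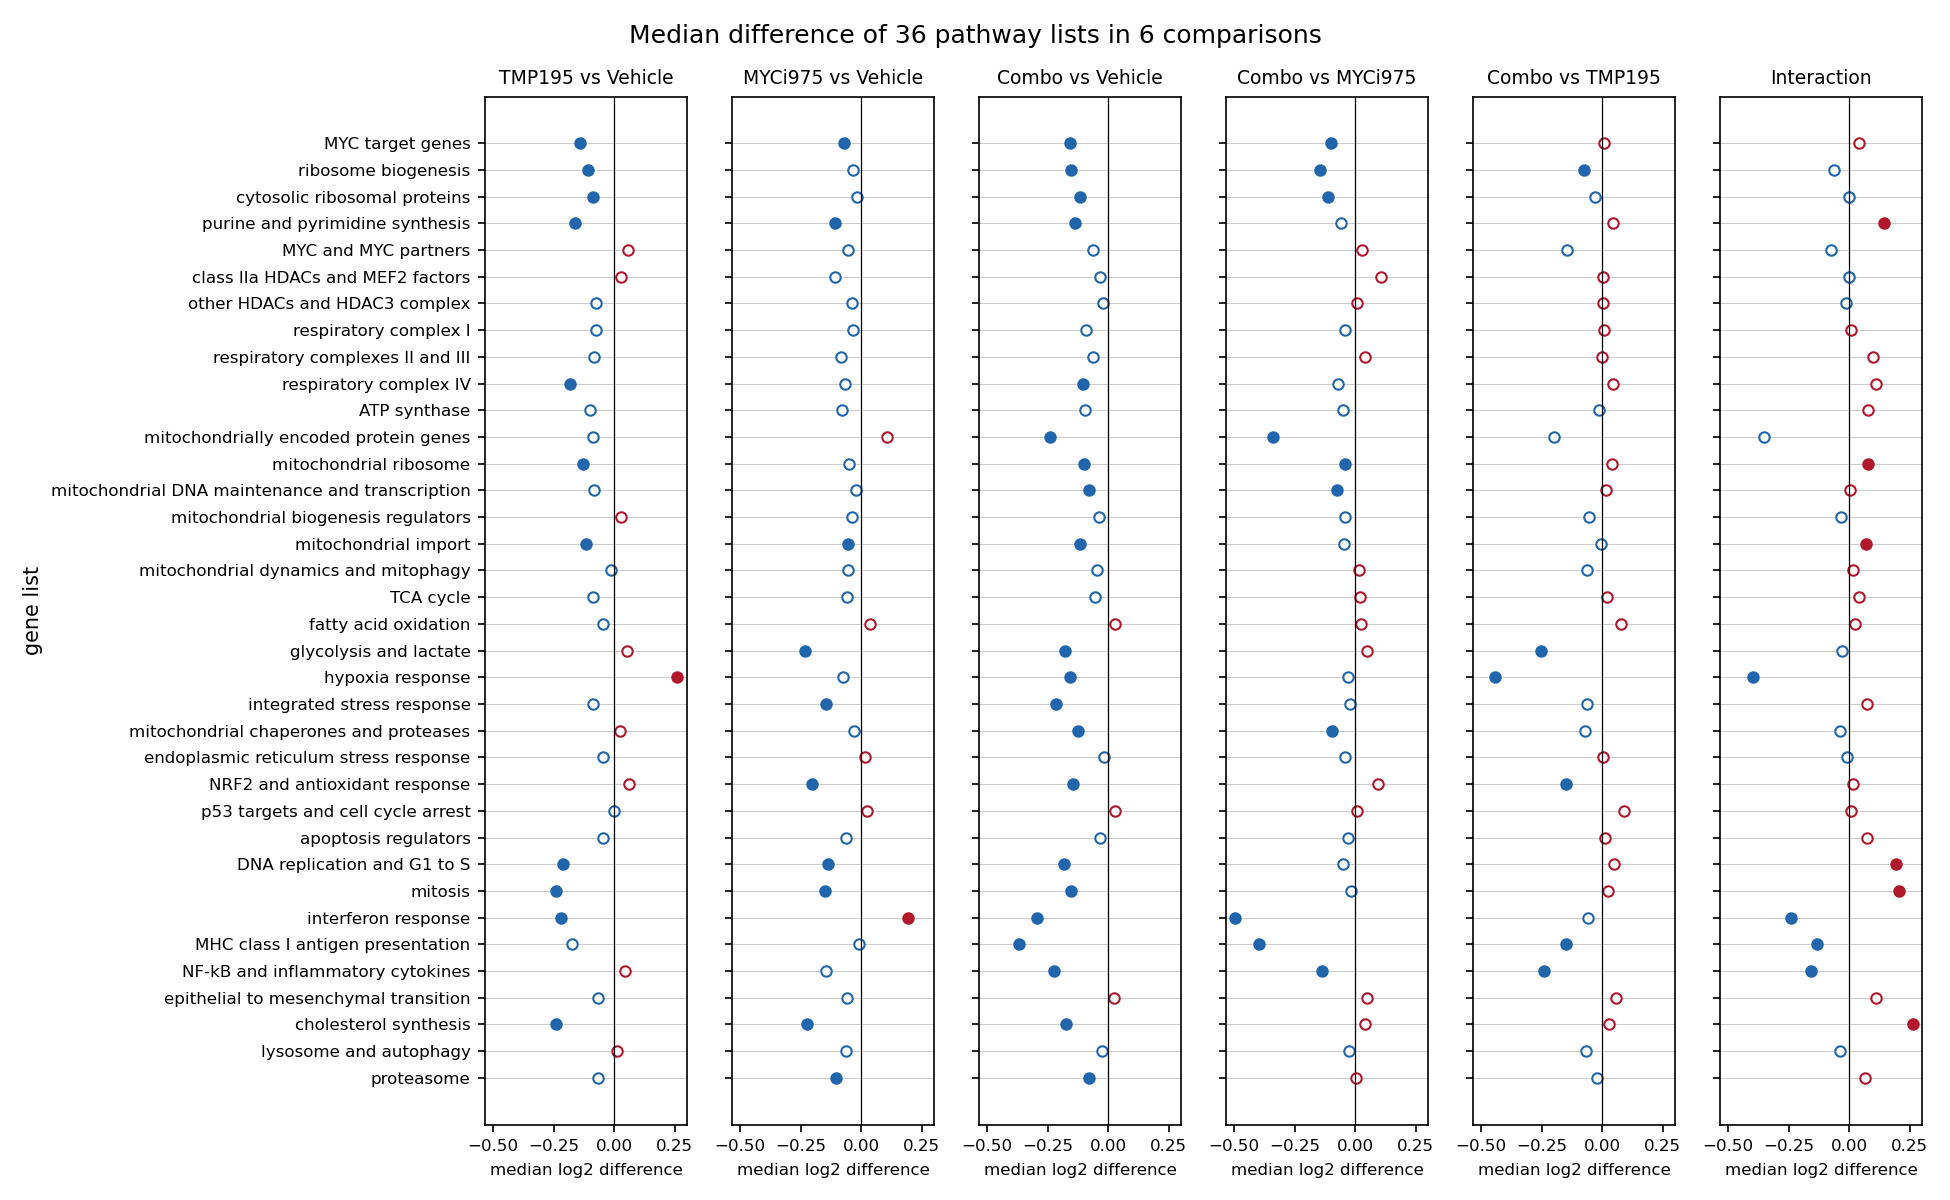
Median log2 difference (x axis) of the members of 36 pathway lists (y axis) in each of 6 comparisons, with red points above 0 and blue points below, filled where camera with the preset correlation called the list. For Combo against Vehicle 21 of the 36 points are filled, all below 0.

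Combo was compared with MYCi975 to ask what TMP195 adds to MYC inhibition. Interferon and antigen presentation genes were lower in Combo, as were ribosome genes. All 43 interferon response genes were lower with a median of -0.50 (camera adjusted p = 2.19e-18; adjusted p = 0.436 with an estimated correlation), including Oas2 (-0.84, SE 0.33), Ifit1 (-0.80, SE 0.42), Usp18 (-0.74, SE 0.34) and Rtp4 (-0.66). The list means of the libraries overlapped, at 8.745, 8.657, 9.788 and 9.267 in MYCi975 and 8.659, 8.831, 8.778 and 8.249 in Combo. Of 36 pathway lists, 1 had an exact permutation p under 0.05 here, and it was not this list. All 21 MHC class I genes were lower with a median of -0.40 (adjusted p = 1.57e-07; adjusted p = 0.513 with an estimated correlation), for example Nlrc5 (-0.82, SE 0.36) and H2-K1 (-0.56). Ribosome biogenesis was lower in 44 of 47 genes (median -0.14, adjusted p = 1.3e-08; adjusted p = 0.208 with an estimated correlation), including Wdr3 (-0.35) and Rrp1b (-0.32, SE 0.13), and ribosomal proteins in 65 of 83 (median -0.11, adjusted p = 3.37e-06; adjusted p = 0.513 with an estimated correlation), including Rpl35 (-0.84, SE 0.24) and Rps16 (-0.65, SE 0.23). MYC target genes had a median of -0.10 (adjusted p = 0.000142; adjusted p = 0.436 with an estimated correlation), with Ppan at -0.40 (SE 0.14).

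The protein genes of the mitochondrial genome were lower in 10 of 13 cases, with a median of -0.34 (camera adjusted p = 0.000219; adjusted p = 0.677 with an estimated correlation), including mt-Atp6 (-0.76, SE 0.32) and mt-Nd4l (-0.60, SE 0.27). Mitochondrial chaperones and proteases (median -0.09, adjusted p = 0.325 with an estimated correlation; fry adjusted p = 0.0251), mitochondrial DNA maintenance (-0.07, adjusted p = 0.436 with an estimated correlation), the mitochondrial ribosome (-0.04, adjusted p = 0.842 with an estimated correlation) and NF-kB genes (-0.14, adjusted p = 0.998 with an estimated correlation) were also called as lower. Neutrophil markers were lower in 8 of 8 cases (median -0.52, adjusted p = 0.000354; adjusted p = 0.394 with an estimated correlation), fibroblast markers higher (0.20, adjusted p = 0.394 with an estimated correlation; -0.019 without MYCi975 replicate 3) and histones lower (-0.18, adjusted p = 0.394 with an estimated correlation). The genes with the smallest p were Timm22 (0.85, SE 0.21), Pdlim4 (0.59), Cyp46a1 (0.66), Hoxc8 (0.74), Armc2 (-0.60) and Ptpn22 (0.64), each with a limma adjusted p of 1. Of the 10 called pathway lists, all lower, none was called with an estimated correlation and fry called 1 of 36. Without MYCi975 replicate 3, genes of the mitochondrial genome (median -0.161), neutrophil markers (-0.134), mitochondrial chaperones (-0.06) and fibroblast markers were not called, and the interferon response was called at -0.274. Without MYCi975 replicate 2, MYC target genes (-0.049), mitochondrial DNA maintenance (-0.038), chaperones and the mitochondrial ribosome were not called, and the median of MYC target genes also moved by over 1.5 times without Combo replicate 2. Without MYCi975 replicate 4 the mitochondrial ribosome (-0.009) and NF-kB genes (-0.039) were not called. Calls were also lost for the mitochondrial ribosome without Combo replicate 2 or 3, chaperones without Combo replicate 1 or 2 or MYCi975 replicate 1, and mitochondrial DNA maintenance without Combo replicate 1 or 4. The same held for NF-kB genes without Combo replicate 2, 3 or 4 or MYCi975 replicate 1 or 3, and fibroblast markers without Combo replicate 2, 3 or 4 or MYCi975 replicate 1. Histones were called at -0.11 without Combo replicate 2, and moved by over 1.5 times without MYCi975 replicate 3 or 4. With quantile normalisation mitochondrial chaperones (-0.091), mitochondrial DNA maintenance (-0.063), the mitochondrial ribosome (-0.029) and fibroblast markers (0.202) were not called, and 7 pathway lists were. With the leukocyte covariate NF-kB genes (-0.046), the mitochondrial ribosome (-0.036) and fibroblast markers (0.175) were not called, and the interferon response (-0.322) and neutrophil markers (-0.327) were called with medians nearer 0. Without the 2 libraries highest in leukocyte markers, chosen after the data were seen, NF-kB genes (-0.087), chaperones (-0.06), genes of the mitochondrial genome (-0.161), neutrophil (-0.134) and fibroblast markers (-0.019) were not called. The interferon response (-0.274) and histones (-0.117) were then called. These medians are by construction those without MYCi975 replicate 3, since the other library is not in this comparison. Without all libraries numbered 4, also chosen then, NF-kB genes (-0.018), mitochondrial DNA maintenance (-0.099) and the mitochondrial ribosome (-0.036) were not called, and MHC class I (-0.221) and the interferon response (-0.325) were. Without MYCi975 replicate 2 camera called 6 pathway lists and limma called 1 gene, Gm15801 (-1.77, adjusted p = 0.0431).

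Combo was compared with TMP195 to ask what MYC inhibition adds to class IIa HDAC inhibition. Hypoxia, glycolysis and inflammatory genes and leukocyte markers were lower in Combo. Of 24 hypoxia response genes, 23 were lower with a median of -0.44 (camera adjusted p = 2.97e-15; adjusted p = 0.367 with an estimated correlation), and 10 passed when adjusted over the list alone against 0 over all genes. The list means ran from 10.655 to 10.867 in Combo (exact permutation p = 0.0286, adjusted p = 0.515). TMP195 replicates 2 and 3 lay farthest above these, at 11.466 and 11.377, with replicates 1 and 4 at 10.915 and 10.992. Car9 differed by -0.97 (SE 0.20, limma adjusted p = 0.325), Ero1l by -0.79 (SE 0.26), Adm by -0.78 (SE 0.26) and Ndrg1 by -0.72 (SE 0.25). Glycolysis genes were lower in 18 of 23 cases with a median of -0.25 (adjusted p = 5.95e-07; adjusted p = 0.531 with an estimated correlation), including the lactate exporter Slc16a3 (-0.69, SE 0.19), Pfkp (-0.63, SE 0.19), Pfkfb3 (-0.62) and Pdk1 (-0.57, SE 0.19).

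NF-kB and inflammatory genes were lower in 24 of 26 cases, with a median of -0.24 (camera adjusted p = 8.08e-08; adjusted p = 0.531 with an estimated correlation), and 2 passed when adjusted over the list alone. The chemokine genes Cxcl3 (-1.40, SE 0.32), Cxcl5 (-1.02, SE 0.35) and Cxcl2 (-0.96, SE 0.49) and the cytokine gene Il1b (-1.58, SE 0.68) differed most. NRF2 genes had a median of -0.15 (adjusted p = 5.08e-06; adjusted p = 0.531 with an estimated correlation), with Hmox1 at -0.76 (SE 0.32) and Gclc at -0.38 (SE 0.11). MHC class I (-0.15, adjusted p = 0.93 with an estimated correlation) and ribosome biogenesis (-0.08, adjusted p = 0.7 with an estimated correlation) completed the 6 called pathway lists. With the leukocyte covariate camera called 4, without NF-kB genes (-0.062), ribosome biogenesis (-0.041) and MHC class I, whose median was above 0 (0.228). Ribosome biogenesis was also not called with quantile normalisation (-0.076, adjusted p = 0.0511), nor, like MHC class I (-0.041), without the 2 libraries highest in leukocyte markers (-0.053). The medians of that last setting are by construction those without TMP195 replicate 1, since the other library is not in this comparison. MHC class I was not called without TMP195 replicate 1 (-0.041) or 3 or Combo replicate 4. Ribosome biogenesis was not called without Combo replicate 2 (-0.043), 3 or 4 or TMP195 replicate 1, and glycolysis was called at -0.163 without TMP195 replicate 3.

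Macrophage and monocyte markers fell in Combo relative to TMP195. Of 12 markers 11 were lower with a median of -0.50 (camera adjusted p = 2.56e-10; adjusted p = 0.0379 with an estimated correlation; fry adjusted p = 0.0401), and 8 passed when adjusted over the list alone. This was the one list, over all 6 comparisons, that was called with an estimated correlation, adjusted over the 9 other lists of this comparison. The list means of the libraries overlapped, since TMP195 replicate 3 (7.41) lay below Combo replicate 2 (7.491). Of the 9 lists, 2 had an exact permutation p under 0.05, and this list was not among them. The splits of the libraries given below were not run for these lists. The markers of all leukocytes had a median of -0.81 (adjusted p = 8.8e-08; adjusted p = 0.0567 with an estimated correlation) with 7 of 9 passing when adjusted over the list alone, neutrophil markers -0.56 (adjusted p = 6.52e-06; adjusted p = 0.111 with an estimated correlation) and dendritic cell and MHC class II markers -0.53 (adjusted p = 1.57e-05; adjusted p = 0.0567 with an estimated correlation). Ptprc differed by -1.40 (SE 0.43, limma adjusted p = 0.633). Fibroblast markers were higher with a median of 0.31 (adjusted p = 0.00202; adjusted p = 0.111 with an estimated correlation), as were early stress genes (0.21, adjusted p = 0.619 with an estimated correlation; -0.05 without Combo replicate 4) and histones (0.10, adjusted p = 0.619 with an estimated correlation; -0.011 without TMP195 replicate 1). Early stress genes were also not called without Combo replicate 1 or 2 or TMP195 replicate 2, 3 or 4, and histones not without Combo replicate 1, 3 or 4 or TMP195 replicate 2. Without TMP195 replicate 1 the markers of all leukocytes were called at -0.40 and those of dendritic cells at -0.349. Both values, and that of histones (-0.011, not called), were the same by construction without the 2 libraries highest in leukocyte markers. With the leukocyte covariate macrophage markers were called at -0.248 (adjusted p = 0.0232). Those of all leukocytes (-0.002), dendritic cells (-0.164), neutrophils (0.123), fibroblasts (0.156) and histones (0.027) were then not called. Early stress genes (0.158) and histones (0.077) were not called with quantile normalisation, and early stress genes (-0.015) not without all libraries numbered 4.

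The gene nearest the threshold was again Cd93 (-1.05, SE 0.16, limma adjusted p = 0.0787), followed by Rnf182 (0.97, SE 0.19), Gpcpd1 (-0.63), Ror1 (0.82), Car9 and Atp8b4 (-0.79), each with an adjusted p of 0.325. With sample quality weights limma called 65 genes, 43 lower and 22 higher, including Cd93 (-1.07, adjusted p = 0.0164), Car9 (-1.01), Adm (-1.06), Ero1l (-1.01), Ndrg1 (-1.03), Pfkp (-0.89), Pdk1 (-0.70), Cxcl3 (-1.36) and Cxcl5 (-1.45). Cd93 was called without an intensity trend (adjusted p = 0.0487) and without Combo replicate 4 (adjusted p = 0.0381), Csf1r and Ccr2 without TMP195 replicate 3 (adjusted p = 0.0211 and 0.0304), and Pdk1 without the 2 libraries highest in leukocyte markers, TMP195 replicate 1 and MYCi975 replicate 3 (-0.81, adjusted p = 0.00463). Without TMP195 replicate 4 camera called 10 pathway lists.

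The interaction asked whether the combination differed from the sum of the single treatments. Hypoxia genes lay below that sum and genes of sterol synthesis and cell division above it. For cholesterol synthesis the group mean was 10.413 in Vehicle against 10.197 in TMP195, 10.195 in MYCi975 and 10.241 in Combo. For mitosis it was 10.77 against 10.551, 10.609 and 10.594, and for DNA replication 10.196 against 9.97, 10.071 and 10.035. The same Vehicle libraries enter each comparison against Vehicle and the interaction. Lower lists there and a positive interaction here are thus not separate results. Hypoxia response genes were lower in 21 of 24 cases with a median of -0.40 (camera adjusted p = 2.86e-06; adjusted p = 0.765 with an estimated correlation), with Car9 at -1.02 (SE 0.29) and Adm at -0.76. Cholesterol synthesis was higher in 22 of 23 genes with a median of 0.26 (adjusted p = 1.25e-05; adjusted p = 0.765 with an estimated correlation), including Nsdhl (0.48) and Cyp51 (0.46). Mitosis had a median of 0.21 (adjusted p = 7.16e-05), DNA replication 0.19 (adjusted p = 8.81e-05), nucleotide synthesis 0.14 (adjusted p = 0.013), the mitochondrial ribosome 0.08 (adjusted p = 0.0466) and mitochondrial import 0.07 (adjusted p = 0.027), each with an adjusted p of 0.765 with an estimated correlation. Examples are Anln (0.55), Rrm2 (0.54, SE 0.21), Tk1 (0.48, SE 0.22), Mcm10 (0.46, SE 0.21) and Timm22 (0.92, SE 0.30).

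Interferon response genes (median -0.24, camera adjusted p = 0.00139; adjusted p = 0.765 with an estimated correlation), NF-kB genes (-0.16, adjusted p = 0.00342; adjusted p = 0.765 with an estimated correlation) and MHC class I genes (-0.13, adjusted p = 0.0466; adjusted p = 0.78 with an estimated correlation) were lower, with Il1b at -2.32 (SE 0.97), Cxcl3 at -1.61 (SE 0.45), Oas2 at -0.77 and H2-Q7 at -1.23. Leukocyte markers (-0.93, adjusted p = 1.77e-06), neutrophil markers (-0.91, adjusted p = 1.61e-07) and macrophage markers (-0.41, adjusted p = 1.48e-05) were lower, each with an adjusted p of 0.0976 with an estimated correlation. The genes with the smallest p were Hoxc8 (1.22, SE 0.26), Ptpn5 (-1.27, SE 0.29), Xylt1 (-1.29, SE 0.31), Cd93 (-0.92, SE 0.23), Ccl6 (-1.49, SE 0.39) and Acvr2b (-0.62), each with a limma adjusted p of 1. Of the 10 called pathway lists, 6 were higher and 4 lower. Without MYCi975 replicate 3 camera called 5, and with the leukocyte covariate it called 6. The interferon response was then called in the opposite direction (0.295, adjusted p = 2.95e-05), and MHC class I was above 0 and not called (0.256). Calls were also lost there for mitosis (0.098), nucleotide synthesis (0.068), import (0.099), NF-kB genes (-0.062), histones (0.064) and the markers of all leukocytes (-0.046), neutrophils (-0.218), macrophages (-0.136) and dendritic cells (-0.043). DNA replication was called at 0.112. With quantile normalisation camera called 7 pathway lists, without MHC class I (-0.122), import (0.038) and the mitochondrial ribosome (0.048), and early stress genes (0.163) were not called.

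Of the settings chosen after the data were seen, the interaction without the 2 libraries highest in leukocyte markers had the interferon response at 0.139 and MHC class I at 0.019, neither called. NF-kB genes (-0.152, adjusted p = 0.051), import (0.088), nucleotide synthesis (0.113) and histones (0.069) were not called either. Leukocyte (-0.393) and neutrophil markers (-0.583), cholesterol synthesis (0.175) and mitosis (0.122) were called with medians nearer 0. Without all libraries numbered 4, DNA replication (0.094), import (0.082), the mitochondrial ribosome (0.052), nucleotide synthesis (0.097) and early stress genes (0.104) were not called, and cholesterol synthesis (0.168) and dendritic cell markers (-0.215) were.

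In the interaction hypoxia response (nearest 0 at -0.267), macrophage (-0.30), neutrophil (-0.675) and dendritic cell markers (-0.254) were called without any 1 library. Leukocyte markers (-0.587) and cholesterol synthesis (0.159) without TMP195 replicate 1, and mitosis (0.122) without Vehicle replicate 4, were called with smaller medians. The same held for cholesterol synthesis without Vehicle replicate 4 and mitosis without Vehicle replicate 2 or TMP195 replicate 1. Not called were DNA replication without Vehicle replicate 4 (0.103; its median also moved by over 1.5 times without TMP195 replicate 2), the interferon response without MYCi975 replicate 3 (-0.002), Combo replicate 4, TMP195 replicate 1 or Vehicle replicate 3, and NF-kB genes without MYCi975 replicate 4 (-0.06) or TMP195 replicate 3. The call of the mitochondrial ribosome was lost without any of 10 single libraries: Vehicle replicate 4 (0.048), 1 or 2, TMP195 replicate 2 or 3, MYCi975 replicate 1, 2 or 3, or Combo replicate 1 or 4. MHC class I was not called without TMP195 replicate 1 (-0.002) or 3, Vehicle replicate 1 or 3, MYCi975 replicate 3 or 4, or Combo replicate 3 or 4. Early stress genes were not called without Combo replicate 4 (0.001), MYCi975 replicate 1, 2 or 3, TMP195 replicate 2 or 3, or Vehicle replicate 3 or 4. Histones were not called without Vehicle replicate 4 (0.047) or 2, MYCi975 replicate 1 or 2, TMP195 replicate 1 or 2, or Combo replicate 4. Nucleotide synthesis lost its call without Vehicle replicate 2 (0.095) or 4, MYCi975 replicate 3 or 4, or Combo replicate 1. Mitochondrial import lost it without MYCi975 replicate 3 (0.045), Vehicle replicate 1 or 4, TMP195 replicate 2 or Combo replicate 1.

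The changes under the single compounds were compared across genes, which are not independent replicates. Differences from Vehicle under TMP195 and MYCi975 correlated at r = 0.453 with a covariance of 0.0175. Simulated unchanged groups that share 4 Vehicle libraries gave a mean r of 0.464, with 95% of 100 simulations between -0.192 and 0.891, and a mean covariance of 0.0223, and the observed covariance minus that mean was -0.00483. With Vehicle divided 2 and 2 so that no library was shared, the mean r over 6 divisions was -0.0785 (-0.137 to 0.000399), and the mean covariance -0.00494.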

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

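The tests of leukocyte markers and of the first principal component, the exact permutation test of list means and the splits with sample quality weights or by replicate number were chosen only after the result was seen.

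All 35 divisions of the same 8 libraries into 4 and 4 were used, without regard to the replicate numbers. The real one is included in every count below. The question was whether chance could be excluded for the counts of pathway lists, of unadjusted genes and of genes with sample quality weights. With these splits, which ignore the numbers, it could not for any of these. For TMP195 against Vehicle, 11 of 35 splits gave at least the real 12 pathway lists (highest other 21) and 19 at least the real 767 genes at an unadjusted p under 0.05 (highest other 1818). For MYCi975 against Vehicle, 10 splits gave at least 11 lists (highest other 18) and 29 at least 476 unadjusted genes (highest other 2236). For Combo against Vehicle, 3 splits gave at least 21 lists (highest other 21) and 10 at least 642 unadjusted genes (highest other 1307). For Combo against MYCi975, 8 splits gave at least 10 lists (highest other 17) and 26 at least 365 unadjusted genes (highest other 1638). For Combo against TMP195, 22 splits gave at least 6 lists (highest other 12) and 5 at least 837 unadjusted genes (highest other 1636). With sample quality weights, 2 of 35 splits gave at least the real 65 genes (highest other 128), a share of 0.0571. For the interaction, 36 of 100 splits of all 16 libraries, 1 of them real and the rest drawn, gave at least 10 lists (highest other 23) and 81 at least 471 unadjusted genes (highest other 2832).

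The 0 genes called by limma in each comparison cannot be set against other splits, since all 35 (or all 100 for the interaction) reach 0 by construction. The most genes called in another split were 1 in the first 4 comparisons, 10 for Combo against TMP195 and 343 for the interaction. The last points to a structure of the libraries, but what that split followed was not tested, and since it divides all 16 libraries it may in part be treatment. Splits that follow the replicate numbers were looked at too, in the order of the 5 comparisons between groups. Numbers 1 and 2 against 3 and 4 gave 1224, 2236, 814, 1151 and 867 unadjusted genes and 2, 2, 0, 1 and 9 pathway lists. Numbers 1 and 3 against 2 and 4 gave 788, 1683, 525, 996 and 778 genes and 7, 11, 9, 3 and 7 lists, and numbers 1 and 4 against 2 and 3 gave 1259, 794, 501, 521 and 763 genes and 8, 10, 14, 9 and 8 lists. None gave a called gene. Each group holds 1 library of each number, so these splits do not bear on whether the numbers made a difference between the groups. They do belong to the 35 splits, and for MYCi975 against Vehicle the 2236 genes of one were the highest other. Where libraries of a number are alike, such splits widen the range that the real split is set against. For numbers 1 and 4, all 6 of 6 same-numbered pairs correlated over 0.1. Splits that balance the numbers between the sides were not examined alone. For pathway lists the splits that follow the numbers reached the real count for MYCi975 against Vehicle (11) and Combo against TMP195 (6), and in no other comparison.

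The median differences of 16 lists departed from the sum of the single treatments in the interaction by camera with the preset correlation, and none did with an estimated correlation. Among pathways these were cholesterol synthesis (0.263), mitosis (0.206), DNA replication (0.192), purine and pyrimidine synthesis (0.142), the mitochondrial ribosome (0.079) and mitochondrial import (0.068), and, below the sum, hypoxia response (-0.396), interferon response (-0.241), NF-kB and inflammatory cytokines (-0.156) and MHC class I (-0.132). Among the other lists these were all leukocytes (-0.93), neutrophils (-0.906), macrophages and monocytes (-0.407), dendritic cells and MHC class II (-0.377, adjusted p = 0.13 with an estimated correlation), early stress genes (0.25, adjusted p = 0.549 with an estimated correlation) and histones (0.178, adjusted p = 0.603 with an estimated correlation). The interaction shares its Vehicle libraries with each comparison against Vehicle, so its results are not independent of those.

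Of 208 groups of 4 values tested, 16 held a library far from the other 3, where chance gives about 10.4. Vehicle replicate 3 was low in respiratory complexes II and III (9.812, others from 9.985), mitochondrial biogenesis regulators (10.009, others from 10.061), fatty acid oxidation (9.384, others from 9.542) and apoptosis regulators (9.921, others from 10.04). Vehicle replicate 4 was high in all leukocytes (7.095, others to 6.686), macrophages and monocytes (7.625, others to 7.194) and mitochondrial DNA maintenance (9.348, others to 9.263), and low in Max (10.396, others from 10.688). Vehicle replicate 2 was high in the integrated stress response (10.485, others to 10.224), and Vehicle replicate 1 low in endothelial cells and pericytes (7.27, others from 7.398). TMP195 replicate 4 was low in NF-kB and inflammatory cytokines (9.617, others from 10.224) and high in endothelial cells and pericytes (7.72, others to 7.445). TMP195 replicate 1 (11.696, others to 11.52) and MYCi975 replicate 4 (12.194, others to 11.59) were high in early stress genes. MYCi975 replicate 3 was low in respiratory complexes II and III (9.726, others from 9.919), and Combo replicate 1 in fatty acid oxidation (9.473, others from 9.562).

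Leukocyte markers were higher in TMP195 than in Vehicle libraries. The value was not that of 1 library alone, since without TMP195 replicate 1 the median difference of all leukocytes was 0.416 (SE of the list mean 0.185), against 0.753 with it. Whole leukocytes left in the enriched tumour cells may account for it, since macrophage and neutrophil list means rose and fell together within groups over 16 libraries (Pearson r = 0.6, permutation p = 0.00014, adjusted p = 0.00037; Spearman rho = 0.715, p = 0.0014, adjusted p = 0.0037, 8 relations; r = 0.6 without the 2 farthest libraries). The markers of all leukocytes also rose within groups with macrophage markers (r = 0.846, adjusted p = 0.00024), neutrophil markers (r = 0.872, adjusted p = 0.00024) and the interferon response (r = 0.694, adjusted p = 0.026; rho = 0.641, adjusted p = 0.042; r = 0.483 without the 2 farthest libraries). The share of the interferon differences that comes with leukocytes was not settled. The relations with fibroblast markers (r = -0.619, adjusted p = 0.059) and hypoxia response (r = -0.375, adjusted p = 0.27) did not pass. A change in tumour infiltration with treatment and a difference in enrichment between libraries both stay open. Dilution of tumour cell RNA by leukocytes, as a cause of the lower proliferation lists, was not settled by the relation of leukocyte and mitosis means. Within groups r was -0.368 (permutation p = 0.18, adjusted p = 0.21), rho was -0.359, and r was -0.212 without the 2 farthest libraries. The leukocyte mean was 6.756 in Vehicle, 6.857 in MYCi975 and 6.667 in Combo. Dilution would thus not account for the lower mitosis median in Combo (-0.155). For TMP195 that median was -0.141 with the leukocyte covariate and -0.24 without it.

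The score on the first principal component rose with the replicate number in every group, Combo included. Replicate 4 of Vehicle, TMP195 and MYCi975 stood farthest apart on it. Lower depth could be a part of this: within groups the component rose with the number of genes at the lowest value (Pearson r = 0.612, permutation p = 0.044, adjusted p = 0.059; Spearman rho = 0.574, p = 0.048, adjusted p = 0.064), but r was 0.477 without the 2 farthest libraries and the adjusted p did not pass. Reads shared between near-identical copies stay open, because pseudogenes and gene models without a gene name made up 57.5% of the 200 largest loadings against 23.3% of tested genes. That ratio, 2.47, lay between the bounds set for and against. No biological explanation was tested, since the labels give these libraries no more than a number.

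The MYC target list was lower in Combo than in Vehicle libraries. Markers of all leukocytes differed little between Combo (6.667 ± 0.175, SD, n = 4) and Vehicle (6.756 ± 0.228). There was thus little change in leukocyte share that could explain it. With the leukocyte covariate the median was -0.16 (SE of the list mean 0.0413) against -0.158 without it. That fit adds no further test, since means so alike left the covariate little to remove. Chance was not excluded for the count of lists that this list belongs to. The list was also lower with TMP195 alone (median -0.141 against Vehicle) and, by less, with MYCi975 alone (-0.073). The MYCi975 call was lost with quantile normalisation (camera adjusted p = 0.055). Combo against MYCi975 was called at -0.1, but not without MYCi975 replicate 2 (-0.049). The list was not called for Combo against TMP195 or in the interaction. A response to TMP195, to MYCi975 or to the combined compounds stays open as a hypothesis, and these data do not tell them apart.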

How the results depend on the processing

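The alternatives without the 2 libraries highest in leukocyte markers, without all libraries numbered 4 and with protein-coding genes alone were chosen only after the result was seen. Genes called by limma stayed at 0 in all comparisons without a filter, with a stricter filter, with robust moderation, quantile normalisation, median centring, the leukocyte covariate and protein-coding genes. For Combo against TMP195, 65 genes were called with sample quality weights, 1 without an intensity trend and 1 without the 2 leukocyte-high libraries. For Combo against Vehicle, 1 gene (Gm15452, named after its value was seen) was called with the 2 groups alone. Pathway lists called fell to 0 in every comparison with an estimated correlation, and by fry were 3 for Combo against Vehicle, 1 for Combo against MYCi975 and 0 elsewhere. Of the other lists, macrophage markers for Combo against TMP195 were called by both (adjusted p = 0.0379 with an estimated correlation, fry adjusted p = 0.0401). The library means of that list overlapped between the groups. In the TMP195 against Vehicle test the estimate was 0.0789 for MYC target genes, 0.161 for ribosomal proteins and 0.334 for glycolysis. It was 0.358 for hypoxia response and 0.661 for genes of the mitochondrial genome. The preset 0.01 thus treats members of these lists as more independent than estimated. Estimates below 0 included class IIa HDACs (-0.0444) and mitochondrial chaperones (-0.0433). Quantile normalisation gave 12, 8, 15, 7, 5 and 7 pathway lists in the order of the report, and the leukocyte covariate 16, 10, 21, 9, 4 and 6. Of the 95 called results, other lists included, 21 lost the call with quantile normalisation. The interaction gave 6 pathway lists with the leukocyte covariate and 6 without the 2 leukocyte-high libraries, and Combo against Vehicle 12 without all libraries numbered 4. What caused the shifts with the normalisation, the covariate and the libraries left out was not tested.

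Leaving out each library in turn, called genes ranged from 0 to 2 for TMP195 against Vehicle (2 without TMP195 replicate 3), 0 to 1 for MYCi975 against Vehicle, 0 to 0 for Combo against Vehicle, 0 to 1 for Combo against MYCi975 (1 without MYCi975 replicate 2 in both), 0 to 2 for Combo against TMP195 (2 without TMP195 replicate 3, 1 without Combo replicate 4) and 0 to 0 for the interaction. Called pathway lists ranged from 8 to 17, 7 to 15, 13 to 21, 6 to 10, 4 to 10 and 5 to 13 in the same order, the extremes over 1.5 times away being without MYCi975 replicate 1 (7), Vehicle replicate 4 (13), MYCi975 replicate 2 (6), TMP195 replicate 4 (10) and MYCi975 replicate 3 (5). The r of the single-compound changes ranged from 0.327 to 0.572, and was 0.391 with the stricter filter.

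Some list medians changed sign, and the cause was not tested. With the leukocyte covariate these were neutrophils for TMP195 against Vehicle (-0.023), MHC class I (0.228) and neutrophils (0.123) for Combo against TMP195, and interferon response (0.295) and MHC class I (0.256) for the interaction. Leaving out 1 library at a time, histones for Combo against TMP195 ranged from -0.011 (without TMP195 replicate 1) to 0.229, interferon response for MYCi975 against Vehicle from -0.025 (without MYCi975 replicate 3) to 0.365, fibroblasts for Combo against MYCi975 from -0.019 (without MYCi975 replicate 3) to 0.314, and early stress genes for Combo against TMP195 from -0.05 (without Combo replicate 4) to 0.308. Without the 2 leukocyte-high libraries, histones for Combo against TMP195 were at -0.011, interferon response for MYCi975 against Vehicle at -0.025 and fibroblasts for Combo against MYCi975 at -0.019. These repeat the values without TMP195 replicate 1 or MYCi975 replicate 3 by construction, since the other library is not in those comparisons. In the interaction interferon response was 0.139 and MHC class I 0.019. Without all libraries numbered 4, interferon response was 0.122 for TMP195 against Vehicle and 0.02 for Combo against Vehicle, and early stress genes -0.015 for Combo against TMP195.

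With the replicate number as a block (replicate block), 0 genes were called in each comparison, and 13, 11, 22, 10, 6 and 8 pathway lists. Not called with the block were neutrophils for MYCi975 against Vehicle (adjusted p = 0.0582), fibroblasts for Combo against MYCi975 (0.0818), early stress genes for Combo against TMP195 (0.0562), and MHC class I (0.0863) and the mitochondrial ribosome (0.0509) for the interaction. The block changed no other call among the lists called without it. The rule used for pairing, every same-numbered pair correlated over 0.1, was not met. All 6 of 6 pairs did so for number 1 (lowest 0.202) and number 4 (lowest 0.172), 2 of 6 for number 2 and 1 of 6 for number 3, 15 of 24 in all. That rule cannot exclude a batch shared by libraries of a number. The first principal component rose with the number in every group. The splits of the libraries took no account of the numbers, and 9 of 16 libraries correlated best with their own number, a hint from the data alone. What the splits show therefore holds only if the libraries of a number are not paired. Depth is unknown, so its limits were not computed.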
